A study of Homo sapiens with 6 samples.

How the data were processed

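Total RNA from 6 culture dishes of ASPC1-GFP cells, 3 treated with DMSO and 3 with fluvastatin, was reverse transcribed into biotin-labelled single-stranded cDNA with the WT PLUS reagent kit and hybridised to a human transcript array, per the labels' protocols. The values used here are the processed intensity per probe set as deposited by the authors, on a linear scale. The software, background correction and normalization behind these intensities are not given in the sources used here. The medians and quartiles of the arrays were close and not identical, so the values had been scaled between arrays in a way that stays unknown, and changes that affect most transcripts alike cannot be read from them. The median log2 intensity of all genes was 6.98 to 7.03.

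The value table held 27189 probe sets per array, and 5741 control and other probe sets were left out, which left 21448 probe sets of transcripts. Gene symbols came from a table that pairs probe sets with gene identifiers: 17709 probe sets had 1 symbol, 0 had several and 3739 are unnamed here. All 17709 gene identifiers were found in a current gene table and 0 symbols changed. Of several probe sets of a gene (42 probe sets) the one with the highest mean over all arrays was kept, which gave 17687 genes. Some textbook target genes of statins are among the genes not analysed here. Empty cells occurred in 521 probe sets, of which 1 was a probe set of a transcript. No reference genome was used here, and no coordinates are given. Columns of values left unused numbered 0.

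The log2 of each intensity was taken with no pseudocount and no filter on dim probe sets, because the intensities were all positive. limma 3.58.1 in R 4.3.3 fitted 1 mean per group with lmFit, and eBayes moderated the variances (4 residual and 4.06 prior degrees of freedom). Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all 17687 genes, with a threshold of 0.05. Fold changes are fluvastatin over DMSO unless stated, and errors are the SD over 3 arrays or the SE of the log2 change.

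The array table gives no detection calls. A gene was called not above the negative controls in a group when, on each of its arrays, it lay at or below the 95th percentile of the negative control probe sets of that array (534 to 554 with a value of 612, limits of 5.84 to 5.95 on the log2 scale). Where this held for 1 group, the fold is a lower bound, with each array of that group set to the higher of its value and the limit. Of the 501 changed genes 0 were below the limit in both groups, 2 in DMSO only and 2 in fluvastatin only.

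The 30 gene lists, with 673 distinct genes of which 605 were measured, were written from textbook knowledge before the data were examined, as were the tests, the alternatives and the rule for named genes. The results of 2 of these lists are not reported here. They were tested with camera at the preset correlation of 0.01 between genes, adjusted by Benjamini-Hochberg over the lists, and again with an estimated correlation. With an estimate, camera works with the 4 residual degrees of freedom, so its p-values can rise even where the estimate lies under 0.01. The rotation test fry, which asks whether the genes of a list move on balance in one direction, was an alternative. The named genes are 8 sterol-responsive genes, of which 5 were measured; the 12 largest rises and 12 largest falls among genes past the threshold with no overlap between groups; up to 4 members per list with the smallest unadjusted p; and CDH1, VIM, ZEB1, ZEB2, SNAI1, SNAI2 and CDH2. Unnamed probe sets, and symbols that start with LOC, LINC, MIR, SNOR or RNU or with OR and a digit, were kept out of the largest changes. This gave 141 genes. Genes named outside this rule are marked as such.

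The fit was tested on simulated data with the same 17687 genes, the spread of these arrays and 200 genes changed: at an absolute log2 change of 1, 97 of 100 changed genes were called, and at 0.5, 44 of 100, with 12 unchanged genes among 153 calls. Alternatives were a replicate block, 3 other scalings (quantile, median centring, cyclic loess), leaving out the dimmest 25% or 50% of the genes, an intensity trend with a robust prior, array weights, the mean of all probe sets of a gene, every probe set, a test per gene without shared spread and leaving out each array in turn, and for the lists also leaving out genes that another list holds. The test per gene was a Welch test, with a separate variance for each group. Leaving out both arrays numbered 1 and using the background of antigenomic control probe sets with 18 to 24 G or C bases as a covariate were added after seeing the data. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.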

Results

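Gene expression was measured in ASPC1-GFP cells, a line of human pancreatic ductal adenocarcinoma (PDAC) derived from an ascites metastasis. Cells were seeded in triplicate dishes and, 24 h later, received either the solvent DMSO or 5 µM fluvastatin for 48 h. Fluvastatin is a statin, a drug that blocks the mevalonate pathway from which cells make cholesterol and the isoprenoid lipids that are attached to small GTPases. Each group held 3 arrays, and 17687 genes were tested, each through 1 probe set. The median intensity of all genes ranged from 126.0 to 130.9 over the 6 arrays, and between 76.6% and 80.2% of the genes lay above the negative controls of their array. The number of arrays limits the precision of every value below. Nothing in the labels says that the dishes came from separate cultures, so p-values measure only the spread between these samples.

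The arrays separated by treatment. Pearson correlations over all genes ran from 0.9817 to 0.9897 within groups and from 0.9766 to 0.9827 between groups, so that the lowest values within groups overlapped the highest between them. The first principal component carried 37.4% of the variance, with scores of -15.70 to -12.94 for the DMSO arrays and 12.04 to 19.61 for the fluvastatin arrays. The second component carried 23.4% and placed fluvastatin replicate 1, at 20.38, apart from fluvastatin replicates 2 and 3, at -13.94 and -11.53. DMSO replicates 1, 2 and 3 scored 8.98, -0.83 and -3.06 on it.

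The comparison of fluvastatin with DMSO asked which transcripts changed under the drug. Genes of mevalonate and cholesterol synthesis rose together, among them ACAT2, which rose 2.55-fold from a log2 intensity of 8.38 ± 0.14 to 9.73 ± 0.06 (SD, n = 3). The small GTPase RHOB and the mesenchymal transcription factor SNAI2 rose 3.41-fold and 2.30-fold, and the tight-junction gene CLDN3 fell from 8.74 ± 0.04 to 7.58 ± 0.01 (SD, n = 3). At an adjusted p under 0.05 in limma, 303 genes were higher and 198 lower with fluvastatin, 501 in all, and 63 of them changed at least 2-fold, 33 upward and 30 downward. The steepest rises were those of DUSP1, a phosphatase that inactivates MAP kinases, at 4.53-fold and of the retinol dehydrogenase DHRS9 at 4.51-fold, ahead of RHOB, which went from 8.84 ± 0.06 to 10.61 ± 0.06 (SD, n = 3, limma adjusted p = 0.000139). The steepest falls were those of MGAM2, which was 4.05-fold higher in DMSO, of RARRES1, a gene responsive to retinoic acid, at 3.45-fold, and of AGR2, a protein disulfide isomerase of mucus-secreting epithelium, at 3.38-fold. On fluvastatin replicate 1 AGR2 had 5.89, under the negative-control limit of 5.95 for that array, and RARRES1 lay at that limit. The folds of AGR2 and RARRES1 are therefore uncertain. All 501 genes had 3 fluvastatin arrays on one side of the 3 DMSO arrays. Of all genes tested 3865, or 21.9%, had groups that did not overlap, where chance gives 10%. The count moved with single arrays: it was 155 without DMSO replicate 2, 207 without DMSO replicate 1, 275 without DMSO replicate 3, 223 without fluvastatin replicate 3, 263 without fluvastatin replicate 2 and 378 without fluvastatin replicate 1. It was 37 with a test per gene that does not share the spread across genes.

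**Figure D1:**
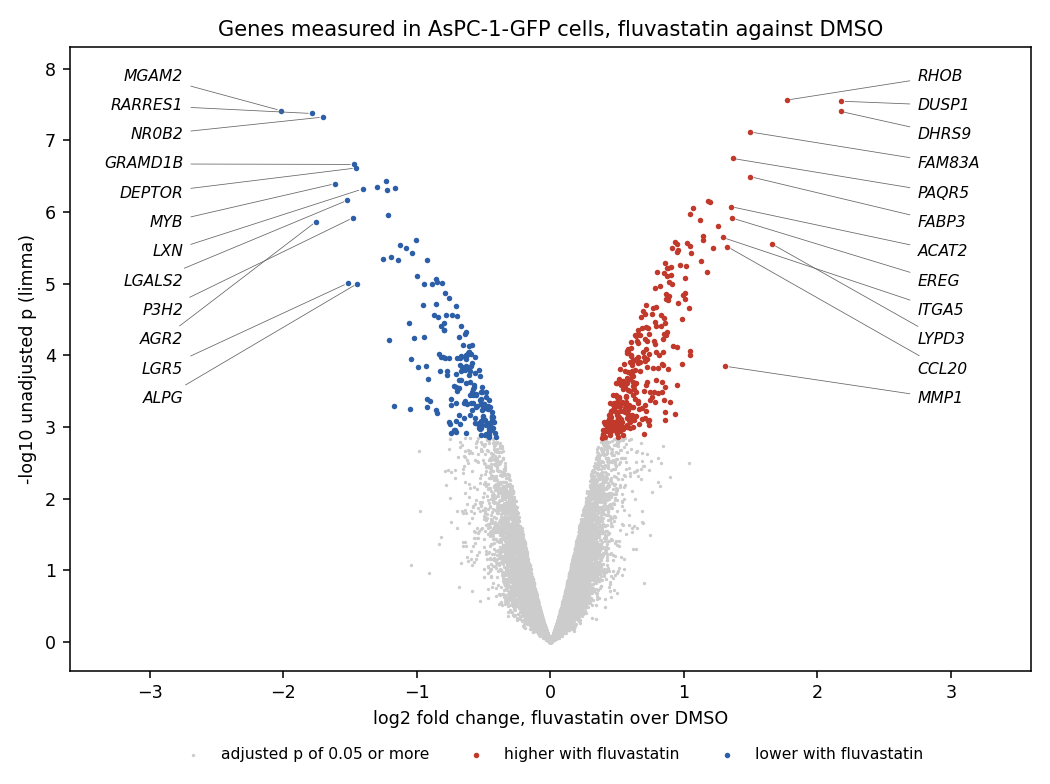
Each point is 1 of the 17687 genes, with the log2 fold change of fluvastatin over DMSO on the horizontal axis and the -log10 unadjusted p of limma on the vertical axis, over 3 arrays per group. Red points are the 303 genes that were higher and blue points the 198 that were lower at an adjusted p under 0.05, and the labels mark the 12 largest rises and the 12 largest falls, from DUSP1 at a log2 fold change of 2.18 to MGAM2 at -2.02.

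Genes that respond to a shortage of sterols were examined first, as a check of the labels. Of the 5 such genes analysed here, 4 rose. HMGCS1, which makes HMG-CoA, went from a log2 intensity of 8.81 ± 0.04 (SD, n = 3) in DMSO to 9.60 ± 0.13 in fluvastatin, a log2 change of 0.79 with a standard error (SE) of 0.10 (limma, adjusted p = 0.00565). SQLE, the squalene epoxidase, rose by 0.79 (SE 0.09, limma adjusted p = 0.00404) and IDI1, the isopentenyl diphosphate isomerase, by 0.78 (SE 0.08, adjusted p = 0.00268). STARD4, a carrier of cholesterol, rose by 0.62 (SE 0.10, limma adjusted p = 0.0152), a call that ended without DMSO replicate 1, 2 or 3 or fluvastatin replicate 3, with adjusted p up to 0.077. INSIG1, which holds the SREBP proteins in the endoplasmic reticulum, had 7.97 ± 0.33 in DMSO and 8.54 ± 0.38 in fluvastatin, with replicate 2 highest in both groups. Its change of 0.57 (SE 0.22) did not pass over all genes (limma unadjusted p = 0.0312, adjusted p = 0.268). Of these 4 calls, 2 held without both arrays numbered 1, an alternative chosen after seeing the data, and 1 with the test that does not share the spread.

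The genes of mevalonate and cholesterol synthesis rose together. Of 19 measured, 11 were higher and none lower over all genes tested, 14 were higher when p was adjusted over the list alone, and 18 had a positive log2 change, with a median of 0.61 (camera, adjusted p = 5.86e-16). ACAT2, which joins acetyl-CoA units at the entry of the pathway, had the steepest rise of the list, 1.35 on the log2 scale (SE 0.10, limma adjusted p = 0.000705). MSMO1, a sterol demethylating oxidase, rose by 0.86 on the log2 scale (SE 0.08, limma adjusted p = 0.00169). SC5D and CYP51A1 had changes of 0.85 and 0.61 that did not pass (limma adjusted p = 0.0576 and 0.133) and had DMSO SDs of 0.36 and 0.37, and LBR was at -0.05. SC5D, CYP51A1 and LBR lie outside the rule for named genes. Of the 30 lists fixed before the data were examined this was the 1 whose call held with a correlation between genes estimated from the arrays (adjusted p = 0.0229). The number of its members past the threshold was 5 without DMSO replicate 2 and between 8 and 10 without any other single array.

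**Figure D2:**
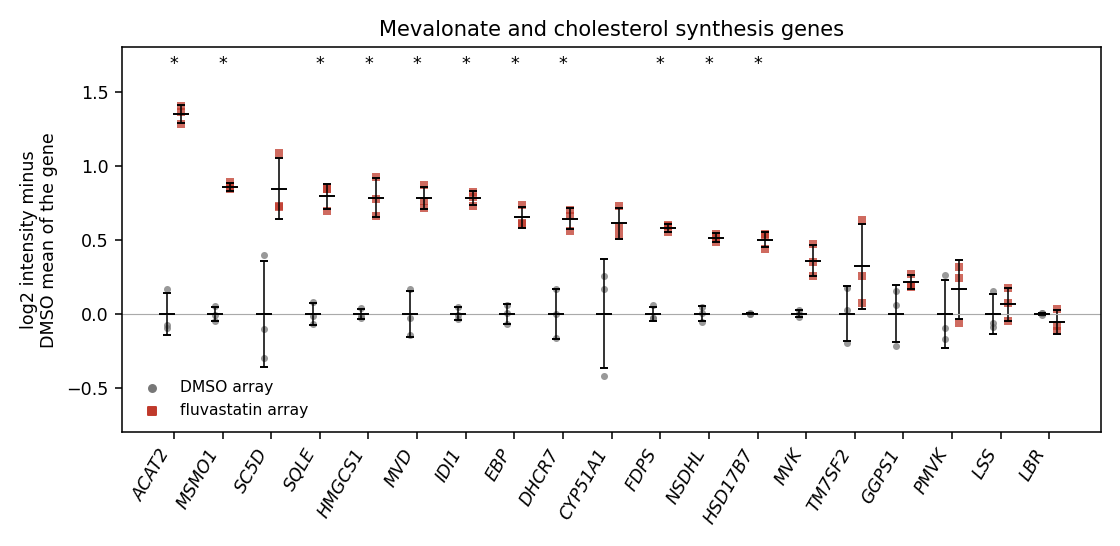
The log2 intensity of 19 genes of mevalonate and cholesterol synthesis is plotted per array, relative to the DMSO mean of each gene, with grey circles for the 3 DMSO arrays, red squares for the 3 fluvastatin arrays and black bars for the mean ± SD of each group. Asterisks mark the 11 genes with an adjusted p under 0.05 in limma, with ACAT2 highest at 1.35, and LBR at -0.05 is the 1 gene with a fluvastatin mean under that of DMSO.

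Other targets of the sterol-regulated factor SREBP2 and genes of sterol uptake were also higher as a group, with 5 of 13 higher, 6 adjusted over the list alone, none lower and a median of 0.33 (camera, adjusted p = 0.000668). With an estimated correlation the adjusted p was 0.127. The members past the threshold were STARD4, ERG28, which anchors sterol-synthesising enzymes (0.71, SE 0.10), TMEM97 (0.57, SE 0.10), the lysosomal cholesterol transporter NPC1 (0.71, SE 0.13) and TRIB3 (0.84, SE 0.12), a pseudokinase also known as a target of the integrated stress response. NPC1 lies outside the rule for named genes and was added after its value was seen. Without single arrays ERG28, TRIB3, TMEM97 and NPC1 lost their calls 3, 3, 5 and 5 times of 6, all of them without DMSO replicate 2 (adjusted p = 0.0652, 0.0653 and 0.11 for the first 3, and up to 0.114 for NPC1). This count fell to 1, 0 and 2 without DMSO replicates 1, 2 and 3, and to 4, 3 and 0 without fluvastatin replicates 1, 2 and 3. Fatty acid synthesis genes did not pass as a list (14 measured, 2 higher and 1 lower, or 4 and 1 adjusted over the list alone, median 0.18, camera adjusted p = 0.109). Within it ACSS2, the cytosolic acetyl-CoA synthetase, rose 2.27-fold (SE of the log2 change 0.09, limma adjusted p = 0.000637). ATP citrate lyase, ACLY, rose by 0.50 and SREBF1, which encodes SREBP1, fell by 0.44 on the log2 scale. Both calls were weak: ACLY lost its call without each array but fluvastatin replicate 1 (adjusted p up to 0.125) and SREBF1 without each of the 6 arrays (up to 0.146).

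None of the 8 genes of protein prenylation and its processing passed the threshold in limma, 1 had an unadjusted p under 0.05 (median 0.04, camera adjusted p = 0.887), and FNTA, a subunit of the prenyl transferases, was at 0.65 (SE 0.24, limma adjusted p = 0.247).

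**Figure D3:**
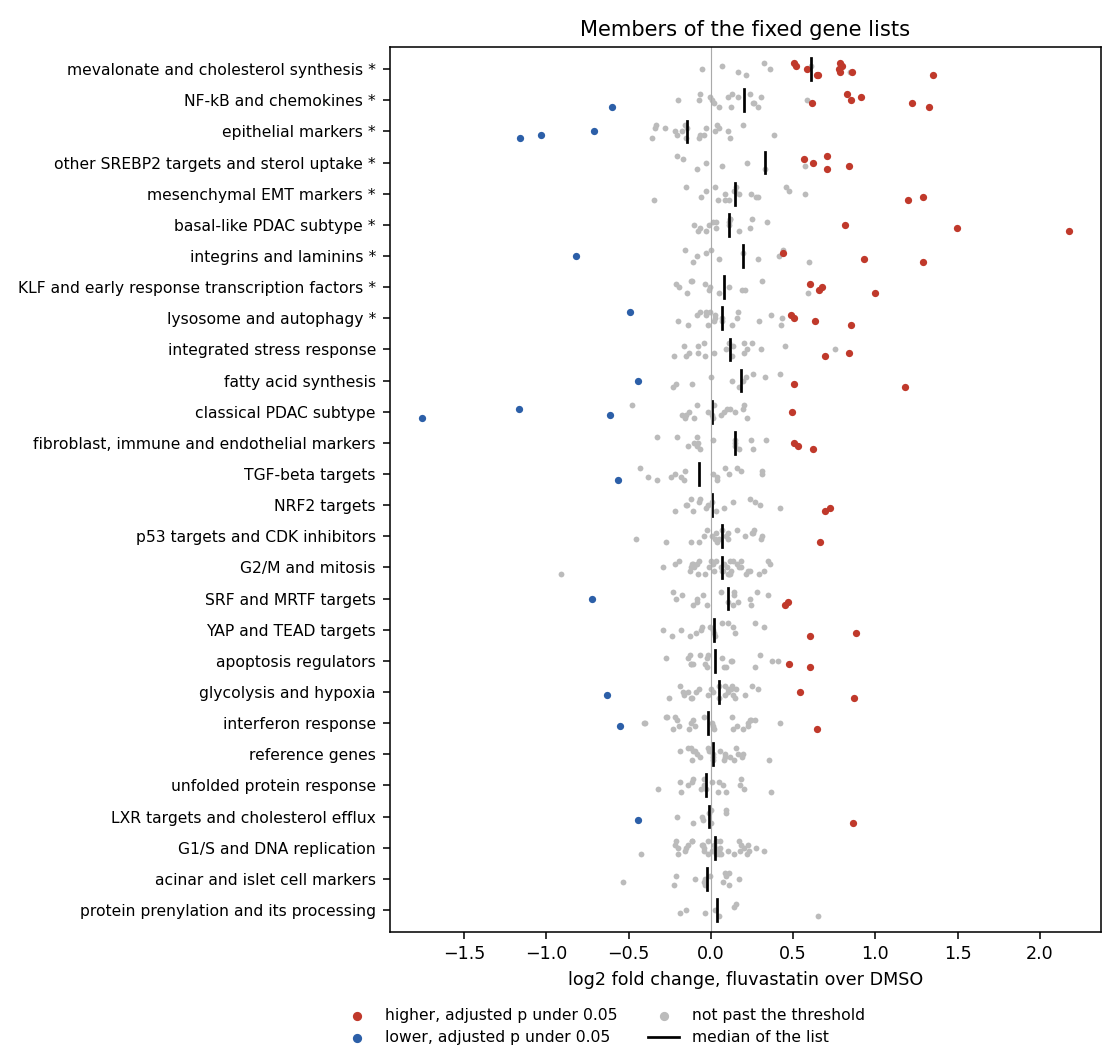
Each row is 1 of 28 gene lists and each dot 1 measured member at its log2 fold change of fluvastatin over DMSO, with 3 arrays per group. Red and blue dots are members higher or lower at an adjusted p under 0.05 in limma, black bars are list medians, and asterisks mark the 9 lists among them past an adjusted p of 0.05 in camera, led by mevalonate and cholesterol synthesis with a median of 0.61.

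Markers of the epithelial state were lower and mesenchymal markers higher, each resting on few genes. Of 24 epithelial markers 3 fell, 5 adjusted over the list alone, and none rose (median -0.14, camera adjusted p = 0.000291, adjusted p = 0.278 with an estimated correlation). The tight-junction claudins CLDN3 and CLDN1 fell by 1.16 (SE 0.08, limma adjusted p = 0.000512) and by 1.03 (SE 0.09, limma adjusted p = 0.00139) on the log2 scale. TJP3, a tight-junction scaffold, fell by 0.71, a call lost without DMSO replicate 1, 2 or 3 or fluvastatin replicate 2 (adjusted p up to 0.163). The E-cadherin gene CDH1 had 7.68 ± 0.12 in DMSO and 7.88 ± 0.095 in fluvastatin (SD, n = 3) and did not pass (limma adjusted p = 0.419). Of 21 mesenchymal markers 2 rose and none fell, or 6 and 1 adjusted over the list alone (median 0.15, camera adjusted p = 0.00195, adjusted p = 0.127 with an estimated correlation). The transcription factor SNAI2 rose 2.30-fold, from 8.97 ± 0.06 to 10.17 ± 0.08 (SD, n = 3, limma adjusted p = 0.000637), and the integrin subunit ITGA5 rose 2.45-fold from a low level, 6.02 ± 0.12 to 7.32 ± 0.14. On DMSO replicate 3 ITGA5 had 5.89, under the negative-control limit of 5.90 for that array. ZEB1 had a change of 0.46 (limma adjusted p = 0.0616) and the filament protein vimentin, VIM, one of 0.28 (adjusted p = 0.135), both without passing. ZEB2 and SNAI1 were at 0.15 and 0.14 (limma adjusted p = 0.57 and 0.539), and the N-cadherin gene CDH2 was not above the negative controls in either group.

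Genes of the PDAC subtypes moved in part. The basal-like list had 3 of 19 members higher, also 3 adjusted over the list alone, and none lower (median 0.11, camera adjusted p = 0.00889). The adjusted p was 0.446 with an estimated correlation and 0.0623 without fluvastatin replicate 1. DHRS9 rose from 8.23 ± 0.09 to 10.40 ± 0.17 and FAM83A, a signalling adaptor downstream of EGFR, from 9.38 ± 0.03 to 10.87 ± 0.06 (SD, n = 3, limma adjusted p = 0.000139 and 0.000192). FGFBP1, which carries fibroblast growth factors, rose by 0.81 (SE 0.11, limma adjusted p = 0.0105), and S100A2 at 0.34 did not pass (adjusted p = 0.153). The classical list did not pass (23 measured, 1 higher, 3 lower, or 1 and 4 adjusted over the list alone, camera adjusted p = 0.159), and its median of 0.007 and its mean of -0.139 differed in sign, with a median down to -0.023 under other scalings. It reached an adjusted p of 0.0426 in camera without DMSO replicate 1. AGR2 fell from 7.91 ± 0.15 to 6.15 ± 0.24 (SD, n = 3, limma adjusted p = 0.000861) and CLRN3 fell by 0.61, a call that ended without DMSO replicate 2 (adjusted p = 0.0613). TSPAN8 fell by 1.17 with a DMSO SD of 0.47 and lost its call when any of the arrays other than DMSO replicate 1 was left out (adjusted p up to 0.107). CTSE rose by 0.49, a call that held without fluvastatin replicate 1 and ended without each of the other arrays (adjusted p up to 0.114).

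**Figure D4:**
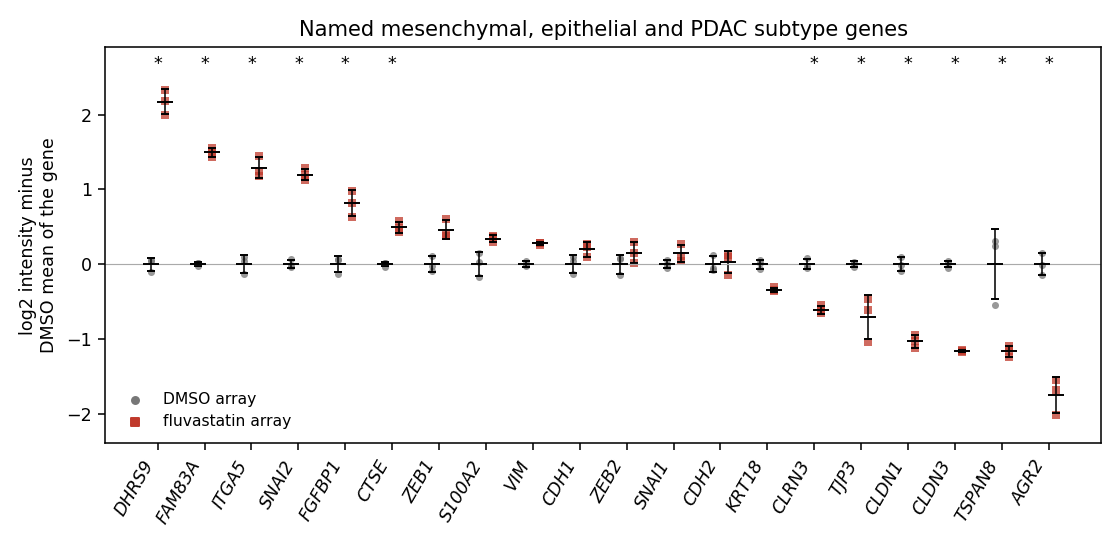
The log2 intensity of 20 named mesenchymal, epithelial and PDAC subtype genes is plotted per array, relative to the DMSO mean of each gene, with grey circles for the 3 DMSO arrays, red squares for the 3 fluvastatin arrays and black bars for the mean ± SD. Asterisks mark an adjusted p under 0.05 in limma, with DHRS9 highest at 2.17, AGR2 lowest at -1.76 and CDH1, VIM and ZEB1 between them without a mark.

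Inflammatory and adhesion genes also changed. In the list of NF-kB targets and chemokines 6 of 24 rose and 1 fell, or 7 and 1 adjusted over the list alone (median 0.20, camera adjusted p = 0.000223, adjusted p = 0.127 with an estimated correlation). The chemokine CCL20 rose 2.51-fold from a log2 intensity of 6.63 ± 0.10 (SD, n = 3). CXCL8 passed too (limma adjusted p = 0.00131), at 7.02 ± 0.095 with fluvastatin, but in DMSO it had 5.80 ± 0.16 (SD, n = 3) and lay under the limit of the negative controls on 2 of 3 arrays, so no fold is given. The deubiquitinase TNFAIP3, which restrains NF-kB, rose from 8.66 ± 0.03 to 9.58 ± 0.13 (limma adjusted p = 0.00243), and IL1B rose by 0.85 (adjusted p = 0.00205). Others past the threshold, named after their values were seen, were IL32 at 0.82, which held without each array in turn, IL1A, and TNFAIP2 at -0.60. IL1A rose from a DMSO mean of 5.81 under that limit, so no size is given. IL1A and TNFAIP2 held only without fluvastatin replicate 1 (limma adjusted p up to 0.0963 and 0.063 without the others). The inhibitor NFKBIA, a direct target also named after its value was seen, was at -0.20 (limma adjusted p = 0.47). Of 15 integrins and laminins 3 rose and 1 fell, or 6 and 1 adjusted over the list alone (median 0.19, camera adjusted p = 0.0109, adjusted p = 0.168 with an estimated correlation). ITGA2 rose 1.91-fold (SE of the log2 change 0.08, limma adjusted p = 0.00131), ITGA5 as above, and ITGB8 fell by 0.82 on the log2 scale (SE 0.10, adjusted p = 0.00614). ITGA3 at 0.44 lost its call without each array in turn (adjusted p up to 0.172).

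The list of KLF and early response transcription factors had 4 of 18 higher, also 4 adjusted over the list alone, and none lower (median 0.08, camera adjusted p = 0.0275, adjusted p = 0.446 with an estimated correlation). JUN rose 1.99-fold (limma adjusted p = 0.00319), and KLF2, KLF6 and FOSL1 rose by 0.65, 0.67 and 0.60 on the log2 scale. KLF6 and FOSL1 missed the threshold without DMSO replicate 2 (adjusted p = 0.0502 and 0.0558). The list itself did not pass without DMSO replicate 3 (adjusted p = 0.165), fluvastatin replicate 1 (0.0612) or fluvastatin replicate 3 (0.0653). Of 25 genes of lysosome and autophagy 4 rose and 1 fell, or 7 and 1 adjusted over the list alone (median 0.07, camera adjusted p = 0.045, adjusted p = 0.446 with an estimated correlation). WIPI1, which binds phosphoinositides at forming autophagosomes, rose 1.81-fold (limma adjusted p = 0.00713), while the lysosomal protease CTSD, named after its value was seen, fell by 0.49, a call that held only without DMSO replicate 3 (adjusted p up to 0.192 without the others). That list passed without DMSO replicate 1 and did not pass without any other single array, with an adjusted p of up to 0.185.

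Cell cycle genes did not change at this threshold. None of 37 genes of G1/S and DNA replication and none of 40 genes of G2/M and mitosis passed in limma, where 4 and 7 had an unadjusted p under 0.05 (camera adjusted p = 0.801 and 0.384). The first list had a median of 0.02 and a mean of 0.01 although camera put it below the other genes. Its lowest unadjusted p belonged to E2F8, at -0.43 (limma adjusted p = 0.106), and that of the second list to CDC20, at 0.30 (adjusted p = 0.124). CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose by 0.66, a call that held without fluvastatin replicate 1 and ended without each other array (adjusted p up to 0.125), and it was the 1 gene of 23 p53 targets and CDK inhibitors that passed (camera adjusted p = 0.288). The integrated stress response list had 2 of 22 higher, TRIB3 and the cystine transporter SLC7A11 (camera adjusted p = 0.109, and 0.037 without fluvastatin replicate 2), and none of 19 genes of the unfolded protein response passed in limma, 2 with an unadjusted p under 0.05 (camera adjusted p = 0.73). TRIB3 lost its call without DMSO replicates 2 or 3 or fluvastatin replicate 3 (adjusted p up to 0.0653). Among 19 NRF2 targets SLC7A11 and TXNRD1 rose (camera adjusted p = 0.267), by 0.69 and 0.72, and lost the call without DMSO replicate 2 and without fluvastatin replicate 2 or 3, respectively (adjusted p = 0.0574, and up to 0.066).

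The remaining lists did not pass in camera. YAP and TEAD targets had 2 of 19 higher, CCN1 and NT5E (adjusted p = 0.51), and SRF and MRTF targets had VCL and ACTN1 higher and FILIP1L lower of 21 (adjusted p = 0.413). TGF-beta targets had 1 of 18 lower, SMAD6, which fell by 0.57 on the log2 scale (camera adjusted p = 0.248 for the list). Apoptosis regulators had MCL1 and TNFRSF10A higher of 22 (adjusted p = 0.533), and glycolysis and hypoxia had ALDOC and NDRG1 higher and CA12 lower of 29 (adjusted p = 0.546). The interferon response had IRF9 higher and PSMB9 lower of 28 (adjusted p = 0.573), and targets of LXR with cholesterol efflux had APOC1 higher and SREBF1 lower of 11 (adjusted p = 0.73), with a median of -0.01 and a mean of 0.02. Of the 15 genes named in these sentences, ALDOC alone held without each array in turn. The others lost the call without at least 1 array, CA12 without DMSO replicate 1 or fluvastatin replicate 3 (adjusted p up to 0.0522) and the other 13 without DMSO replicate 2, for most of them without further arrays too (highest adjusted p from 0.0558 for MCL1 to 0.172 for TNFRSF10A). The medians of the YAP and NRF2 lists changed sign under other scalings, down to -0.014 and -0.026. Reference genes had none of 24 past the threshold in limma and 1 with an unadjusted p under 0.05 (median 0.02, adjusted p = 0.73), with ACTB at 0.16 (limma adjusted p = 0.439).

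Markers of other cell types were read for signs of a mixed culture. None of 14 acinar and islet markers passed in limma, none had an unadjusted p under 0.05 (camera adjusted p = 0.835). Of 19 markers of fibroblasts, immune cells and endothelium 3 were higher, or 4 adjusted over the list alone, and none lower (median 0.15, camera adjusted p = 0.179). LUM, a matrix proteoglycan, went from 9.91 ± 0.10 to 10.53 ± 0.05 and CD68, a lysosomal glycoprotein of macrophages and other cells, from 9.53 ± 0.08 to 10.06 ± 0.035 (SD, n = 3, limma adjusted p = 0.0114 and 0.0181). PTPRC was not above the negative controls in DMSO and at least 1.17-fold higher with fluvastatin (limma adjusted p = 0.0344), where the bound sets each DMSO array at the limit of its negative controls. LUM lost its call without DMSO replicates 1 or 2 (adjusted p up to 0.0558), CD68 without DMSO replicates 1 or 2 or fluvastatin replicates 2 or 3 (up to 0.101) and PTPRC when any one of the 6 arrays was left out (up to 0.135). The collagen gene COL1A1 and the endothelial gene PECAM1, read after the fact, were at 0.15 and -0.20 without passing (limma adjusted p = 0.691 and 0.608).

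The remaining genes among the 12 largest rises were LYPD3 (3.16-fold), the fatty acid binding protein FABP3 (2.82-fold), the membrane progestin receptor PAQR5 (2.57-fold), the EGFR ligand EREG (2.57-fold) and the collagenase MMP1 (2.48-fold). Epiregulin, EREG, went from 7.87 ± 0.17 to 9.23 ± 0.06 (SD, n = 3, limma adjusted p = 0.000824). MMP1 went from 6.30 ± 0.43 to 7.62 ± 0.09 and had an adjusted p of 0.0505 in limma without fluvastatin replicate 2. On DMSO replicate 1 MMP1 had 5.81, under the negative-control limit of 5.84 for that array, so its fold is uncertain. The remaining largest falls, as the fold of DMSO over fluvastatin, were the nuclear receptor NR0B2 (3.25), the transcription factor MYB (3.06), LGALS2 (2.87), the stem-cell receptor LGR5 (2.86), the collagen prolyl hydroxylase P3H2 (2.79), the sterol transporter GRAMD1B (2.77), the mTOR-binding protein DEPTOR (2.74), the alkaline phosphatase ALPG (2.72) and LXN (2.65). NR0B2 fell from 9.78 ± 0.07 to 8.08 ± 0.07 and GRAMD1B from 10.81 ± 0.11 to 9.34 ± 0.06 (SD, n = 3, limma adjusted p = 0.000139 and 0.000425). ALPG has a near-identical copy, ALPP, whose probe set also fell, by 1.22 on the log2 scale (a gene added after its value was seen), so the share of each gene is uncertain. Of the 24 genes with the largest rises and falls, 23 stayed past the threshold without each array in turn, and of all 80 named genes past it 41 did.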

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

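The test of fluvastatin replicate 1 alone was chosen only after its result was seen, and the background covariate after the data were seen but before its own result. Outside the named genes, 67 of 3738 transcript probe sets that are unnamed here passed an adjusted p of 0.05 in limma, 49 higher and 18 lower with fluvastatin, with log2 changes from -1.13 to 1.65. That is 1.79% of them, against 2.74% of the probe sets with a gene symbol in the same fit, which took every probe set. Of 2555 probe sets known only by number 1 passed. What the unnamed transcripts are was not analysed here.

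The 501 changed genes rest on 3 arrays per group, and both arrays numbered 1 had a higher background on antigenomic probe sets of high GC content, 7.30 and 7.23 on the log2 scale against 7.05 to 7.14 for the others. With that background as a covariate the log2 changes of the called genes were 1.007 times their former size at the median (interquartile range 0.967 to 1.048). The background was raised on 1 array of each group, so the covariate could move these changes little. The ratio therefore does not decide whether this background contributed. Fluvastatin replicate 1 stood apart on the second principal component, and 378 genes were called without it, so that it alone does not carry the list. Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many genes, the real one with 501, and the highest of the other splits gave 0, but 10 splits are too few for a share under 0.05. The 19 genes of mevalonate and cholesterol synthesis, a list fixed before the data were examined, rose together without any single array (camera adjusted p up to 1.5e-13). A shortage of sterols under a statin gives this direction. For that list the values therefore go with a response to fluvastatin, the difference that the design names. For the other changed genes such a response stays among the open explanations.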

How the results depend on the processing

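The covariate and leaving out both arrays numbered 1 were chosen after seeing the data. With the covariate, all 501 changed genes kept their direction, which its near balance between the groups made likely beforehand. Under most other alternatives the direction is fixed beforehand, since the groups of these genes do not overlap or the fold is the same. The counts ranged from 382 to 711 under the other scalings, filters, priors, weights and the covariate, and the share of higher genes stayed between 57.1% and 61.2% under scalings, filters and priors. The count was 294 (178 higher, 116 lower) with the replicate number as a block, 280 of them shared with the 501. The labels give same-numbered arrays only the number in common. Deviations of same-numbered arrays correlated at 0.15, 0.05 and 0.01, and 2 of 6 arrays correlated best with their own number. Both arrays numbered 1 had the higher background of high GC content. They also had positive scores on the second principal component, 8.98 and 20.38, where the other arrays had negative ones. An effect shared by the arrays numbered 1 therefore stays open. With a test per gene without shared spread, 37 genes passed (27 higher, 10 lower, 13 at 2-fold or more) and 1 of the sterol-responsive genes; the cause was not tested. Without both arrays numbered 1 the count was 108 (65 higher, 43 lower), with 2 of the sterol-responsive genes, from 2 arrays per group. Without single arrays the counts were 155 to 378, with 95 to 220 higher and 60 to 158 lower, again from fewer arrays.

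Of the 10 gene lists past the threshold 1 passed with an estimated correlation, and 7 to 11 lists passed without single arrays. The setting with an estimate also has fewer degrees of freedom, so calls lost there need not be lost to correlation between genes. The block put the KLF and lysosome lists at an adjusted p of 0.0513 in camera and ended no other list call. Without both arrays numbered 1 the basal-like list did not pass (0.101), while the classical and fatty acid lists did (0.0377 each). fry also called fatty acid synthesis, SRF and MRTF targets, NRF2 targets and fibroblast and immune markers. Correlations within groups exceeded those between groups by 0.0062, by 0.0101 without the dimmest 25% of genes and by 0.0193 without the dimmest 50%; the cause was not tested. Of the 80 named genes past the threshold 11 passed under every alternative and 35 under every one but the test without shared spread. Signal over background limits dim genes: 76.6% to 80.2% of genes lay above the negative controls.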

Other observations

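The gene families, the gastrointestinal list and the receptor targets below, and with them all tests in this part, were chosen only after the changed genes were seen, and of the tests of explanations only that of the histone classes was fixed before its own result was seen. Of 15 S100A genes, which encode small calcium-binding proteins, 4 rose and none fell (median 0.19, camera p = 8.79e-05, and p = 0.0138 with an estimated correlation), among them S100A16, from a DMSO level of 10.42 by 0.80 on the log2 scale (limma adjusted p = 0.00201). Of 11 metallothionein genes, which encode metal-binding proteins of near-identical sequence, 3 rose (median 0.43, camera p = 5.76e-06, and p = 0.116 with an estimated correlation), among them MT2A by 0.57 (limma adjusted p = 0.0392), a call lost without each of the 6 arrays (adjusted p up to 0.139). Of 23 dual specificity phosphatases only DUSP1 and DUSP4 rose and none fell at an adjusted p under 0.05 (median 0.10, camera p = 0.0218, and p = 0.0645 with an estimated correlation). DUSP6, a phosphatase induced by ERK signalling, was at -0.22 without passing (limma adjusted p = 0.283). The medians of these families kept their sign under the 3 other scalings. These p-values are not adjusted for the search over families.

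Replication-dependent histone genes were lower. Of 61 measured 50 had a lower mean with fluvastatin and 3 fell at an adjusted p under 0.05, H2AC19, H4C8 and H2BC8, the last of which held only without fluvastatin replicate 3 (adjusted p up to 0.116 without the others; median -0.27, camera p = 6.97e-11, and p = 0.0244 with an estimated correlation). The list was narrowed from all cluster histones after a first result was seen. The medians relative to DMSO were -0.23, -0.26 and -0.16 on the fluvastatin arrays and -0.04, 0.07 and -0.06 on the DMSO arrays, and the list median stayed between -0.35 and -0.21 without any single array. Fewer cells in S phase could lower replication genes too, and their median was 0.024 (bootstrap interval -0.040 to 0.057). How far a smaller share of cells in S phase would lower those genes is not known here, so this value does not decide the question. A signal shared by the copies of only 1 class would leave the other classes unchanged, but the class medians ran from -0.432 for H2B to -0.155 for H4. Signals shared between near-identical copies within each class stay possible, so the 61 genes may not be independent measurements. The 9 replication-independent histones had a median of -0.019 (bootstrap interval -0.185 to 0.112) and gave a camera p of 0.325, with H2AJ at -0.60 and the others between -0.185 and 0.132, which argues against a like fall of all histone transcripts. Yields of RNA without a poly(A) tail were not tested.

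Among the genes that fell, 14 known from gastrointestinal epithelium were picked out after their values were seen, and no test shows that such genes are more frequent there than others. They include GPA33, which fell by 1.30, HNF4G by 1.08, VIL1 by 1.01 and MUC13 by 0.92 on the log2 scale, besides LGR5, MYB, NR0B2 and LGALS2. The median DMSO level of the 14 lay 1.85 above the highest antigenomic background probe set, and 12 of the 14 lay above it, all but LRRC66 and FOXA1. Genes picked because they fell needed room above the floor in DMSO. These levels describe the 14 and are no separate test of a signal near background. A fall of the wider programme stays open. The other 42 of the 56 measured members had a median of -0.013 and gave a camera p of 0.871, but the 14 were set apart because they had fallen, so these values decide nothing. ANPEP, among the 42, rose by 0.91 on the log2 scale.

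FGF19 and NR0B2, both known targets of the bile acid receptor, fell by 1.21 and 1.70 on the log2 scale. Lower activity of that receptor could account for both, and 18 of its other target genes were tested together: they gave a camera p of 0.171 with a median of 0.13, and their median DMSO level of 5.83 was at the negative controls, so this test leaves the hypothesis open. Of the members with higher DMSO levels, VIPR1, at 8.60, fell by 0.61 on the log2 scale (limma adjusted p = 0.00895, and 0.057 without DMSO replicate 2), while SDC1, at 10.72, and PPARA, at 8.05, had changes of 0.20 and -0.01 that did not pass (limma adjusted p = 0.589 and 0.964).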
